A study of Homo sapiens with 12 samples.

How the data were processed

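RNA from primary human dermal fibroblasts was measured on 12 arrays, 2 for each of 6 groups formed by dose (0, 4 or 12 J/cm2 of simulated sunlight) and recovery (0 or 24 h). Groups were read from the sample labels. Whether the 2 arrays of a group came from separate cultures is not given in the sources used here, so the spread behind each p-value may be technical. Per the labels' protocols, total RNA was amplified, turned into biotin-labelled single-stranded cDNA and hybridised to Affymetrix whole-transcript arrays. The series text names an exon array and a collection at 24 h, whereas the rows carry the probe numbers of a gene array and the sample labels include 0 h, and the rows and labels were followed.

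The deposited values were log2 values that the authors had centred, each row having a median of 0 over the 12 arrays. The software, background correction, summarisation and normalization are not given in the sources used here. The base was inferred from the rounding of the deposited numbers. In most rows the differences between arrays were, within 0.06 of a step, whole multiples of 1 of 2 steps of single-precision numbers. The coarse step, that of values from 8 to 16, fitted 40.6% of rows (called bright), the middle step, that of values from 4 to 8, fitted 51.2% (called dim), a finer step only 0.26%, and 8.2% were unsettled, while 0% of rows with added jitter fitted. Centring removed signal levels, so distance from background could be judged only by this class. Array medians, in the order sham, 4 and 12 J/cm2 and replicates 1 and 2, were -0.0039, -0.0079, -0.0074, 0.169, 0.0019 and -0.0022 at 0 h and -0.0062, -0.0146, -0.0043, -0.0012, -0.0041 and -0.0023 at 24 h.

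Of the rows, 19291 had 1 gene symbol, 1735 several and 7803 none in the probe table. Of those with 1 symbol 19260 matched the reference by gene ID and 0 symbols were updated. XIST and Y-linked genes (94 rows) were left out of every step. The 28735 rows tested held 11695 bright, 14701 dim and 2339 unsettled rows and 18349 distinct genes. No normalization was added in the main analysis.

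A linear model of group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (6 residual and 4.54 prior degrees of freedom, no trend with level because levels were lost, not robust). There were 9 contrasts, namely each dose against sham and 12 against 4 J/cm2 at each time, the difference of each dose's effect between times, and sham at 24 h against 0 h. P-values were adjusted by Benjamini-Hochberg over all rows of a contrast and rows under 0.05 were called. Errors are moderated standard errors. In all, 23 gene lists with 652 genes, of which 606 were measured, were written before the data were examined. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the 23 lists, and again with a correlation estimated from the arrays and with fry. Members were also adjusted over the list alone. Each gene was represented by 1 row, the planned choice of the highest mean being meaningless for centred values and replaced by the brightest class and then the lowest probe number.

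The genes named were fixed by a rule, which took the 10 largest rises and falls (5 in contrasts between doses or times) among called rows with 1 symbol whose groups did not overlap, or the 5 highest and lowest t values where none was called. To these were added MMP1, MMP3 and up to 4 members of lowest p in each list past the threshold and in 6 fixed lists. For doses sharing sham arrays, agreement was compared with 100 simulations of unchanged groups. The method was tested on simulated data with known changes. Changes of 1.5-fold were found in 85.1% to 86.6% of changed rows and those of 2-fold in 97.0% to 100%, with 3 to 7 of the unchanged rows called. A shifted list was found in each of 3 simulations, and 0, 1 and 0 of 22 unshifted lists passed. The simulated rows were independent of each other, so the list test was not tried on correlated genes. At each fold 66 or 67 rows were changed, besides the shifted list, and recovery may be lower where fewer rows change.

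Alternatives tried were robust moderation, rows with 1 symbol only, quantile normalization, cyclic loess, subtracted array medians, the replicate number as a block, only the arrays compared, a change of at least 2-fold, and leaving out each array in turn, and for lists the mean of all rows of a gene. Bright rows only, medians subtracted by class, and omission of replicate 2 of the 4 J/cm2 0 h group from comparisons without that group were added after seeing the data. Quantile normalization and cyclic loess were run on the centred values, so neither adjusted for signal level and both can reduce large changes. Genomic spans came from the NCBI RefSeq gene table. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.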

Results

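Gene expression was measured in primary human dermal fibroblasts, the matrix-producing cells of the skin's deep layer, after a single exposure to simulated sunlight made up mostly of UVA with a small part of UVB. The doses were 0 (sham), 4 and 12 J/cm2, and RNA was taken at 0 h, directly after the exposure, or after 24 h of recovery. Each of the 6 combinations had 2 arrays, 12 in all, and the number of arrays limits the precision of every value. The table gave 28735 tested rows in log2 units, each centred on its own median over the 12 arrays, so that only differences between arrays could be read. Array medians lay between -0.01 and 0.00 on 11 arrays and at 0.17 on replicate 2 of the 4 J/cm2 0 h group. On that array the median was 0.22 over dim rows and 0.12 over bright rows.

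**Figure D1:**
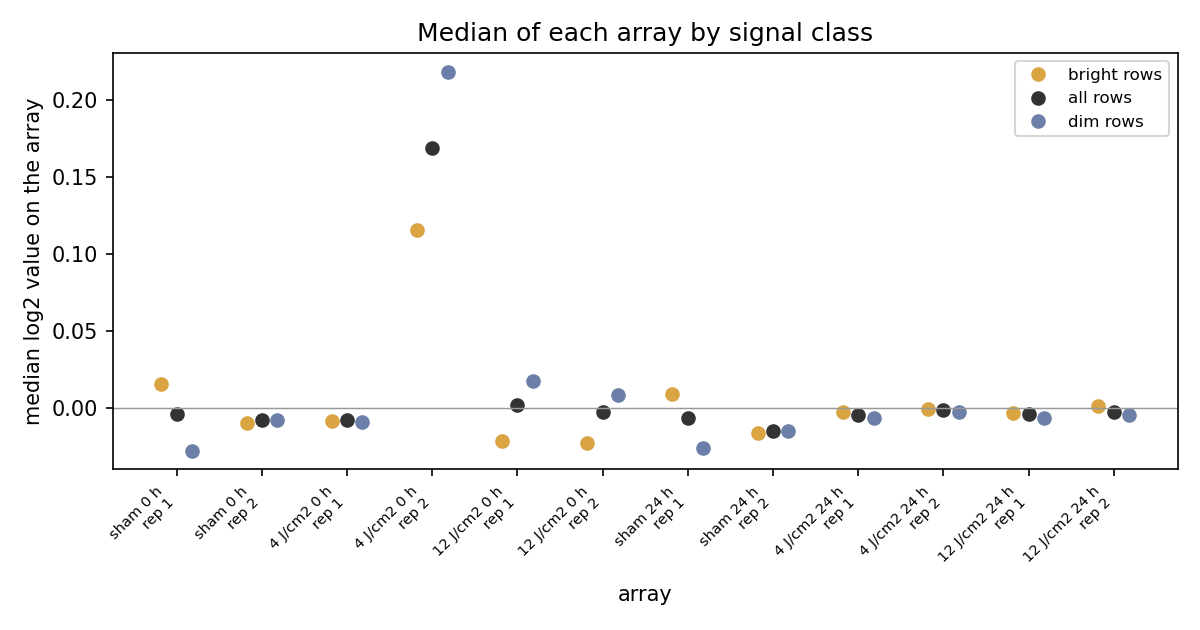
Median log2 value of each of the 12 arrays over bright rows, dim rows and all rows, each row having been centred on its median over the arrays. Replicate 2 of the 4 J/cm2 0 h group lies at 0.17 over all rows, apart from the other 11 arrays.

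The series concerns histone H3 methylation at the promoters of MMP1 and MMP3, which encode interstitial collagenase and stromelysin-1, enzymes that degrade the collagen-rich matrix of the dermis. Directly after exposure neither gene passed at either dose. MMP1 changed by 0.02 ± 0.06 (log2, SE, n = 2 arrays per group) at 4 J/cm2 and by -0.01 ± 0.06 at 12 J/cm2, with limma adjusted p = 0.868 and 0.950. MMP3 changed by 0.02 ± 0.14 and -0.15 ± 0.14, with limma adjusted p = 0.954 and 0.667. After 24 h MMP1 (gene ID 4312) rose 1.45-fold at 4 J/cm2 (0.53 ± 0.06, limma adjusted p = 0.0344) and 2.08-fold at 12 J/cm2 (1.06 ± 0.06, limma adjusted p = 2.98e-05). MMP3 (gene ID 4314) rose 3.56-fold at 12 J/cm2 (1.83 ± 0.14, limma adjusted p = 0.000112). At 4 J/cm2 its value was 1.77-fold that of sham (0.82 ± 0.14), which did not pass over all rows (limma adjusted p = 0.178). Between the doses at 24 h the difference was 0.52 ± 0.06 for MMP1 and 1.01 ± 0.14 for MMP3, with limma adjusted p = 0.0134 and 0.0145. The 12 J/cm2 effect was larger at 24 h than at 0 h by 1.07 ± 0.09 for MMP1 and 1.98 ± 0.20 for MMP3, with limma adjusted p = 0.00140 and 0.00206. The MMP1 call at 4 J/cm2 did not hold without any 1 of the 4 arrays compared (adjusted p up to 0.540), and it was also lost with cyclic loess (adjusted p = 0.0581) and with only those arrays in the fit (adjusted p = 0.0837). The difference between doses did not pass for either gene without either array of the 4 J/cm2 24 h group. Nor did it without replicate 2 of the 12 J/cm2 24 h group or with only these groups in the fit. On leaving out arrays it ranged from 0.48 to 0.57 for MMP1 and from 0.81 to 1.21 for MMP3. With quantile normalization it was 0.05 for MMP1 and -0.05 for MMP3. That method gives every array the same distribution of centred values, and both genes stood far above most rows at both doses. It can remove such a difference by itself and so does not test it.

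**Figure D2:**
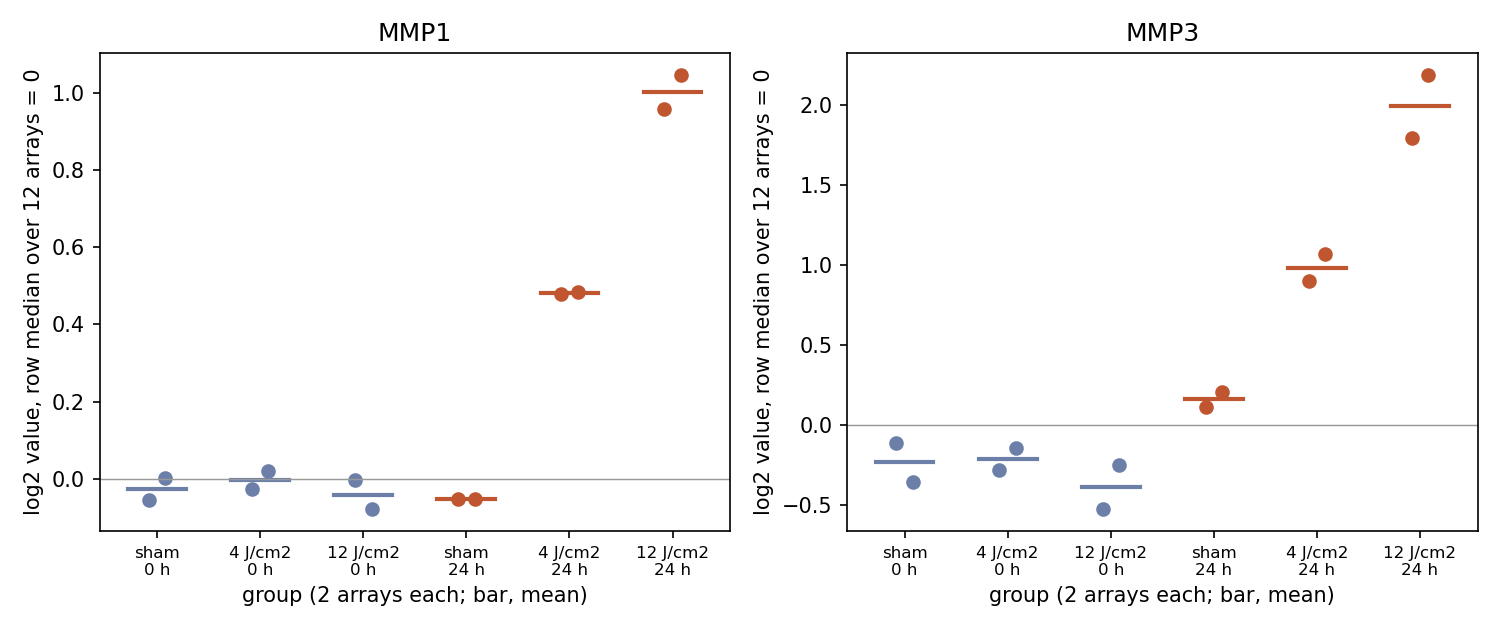
Log2 values of MMP1 and MMP3 on each array (points) and group means (bars), 2 arrays per group, centred on the row median over 12 arrays. At 24 h the MMP1 mean is -0.05 in sham, 0.48 at 4 J/cm2 and 1.00 at 12 J/cm2, and the MMP3 mean is 0.16, 0.98 and 1.99.

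The comparison of 12 J/cm2 with sham at 24 h asked which genes differed a day after the higher dose. The genes with the largest rises were SLC7A8, a transporter of neutral amino acids (2.49 ± 0.13 on the log2 scale, 5.63-fold, adjusted p = 2.98e-05), MMP3 (1.83 ± 0.14) and IL33, an alarmin cytokine (1.83 ± 0.18). DCSTAMP, a membrane protein of cell fusion, rose by 1.78 ± 0.17 and the stress cytokine GDF15 by 1.54 ± 0.15. TFPI2, a protease inhibitor, rose by 1.43 ± 0.14 and the growth factor HGF by 1.33 ± 0.14. MCTP1 rose by 1.22 ± 0.14, the integrin subunit ITGB3 by 1.18 ± 0.10 and the small heat shock protein CRYAB by 1.16 ± 0.17. The largest falls were those of MAMDC2 (-1.98 ± 0.13), PLCB4 (-1.70 ± 0.12), LIPH (-1.62 ± 0.13) and HHIP, a hedgehog-binding protein (-1.60 ± 0.17). TENM2 fell by 1.57 ± 0.17, KRT34 2.84-fold (SE 0.21 on the log2 scale), the vasoconstrictor gene EDN1 by 1.49 ± 0.08 and IGFBP3, which binds insulin-like growth factors, by 1.45 ± 0.08. LCE2B and LCE2C fell by 1.39 ± 0.13 and 1.31 ± 0.15. Cyclic loess, run on centred values, follows a trend with those values rather than with signal level, and can itself reduce large changes. With it LIPH, LCE2B and LCE2C did not pass (adjusted p = 0.155, 0.777 and 0.519). The last 2 have near-identical copies and KRT34 has close relatives, so their signals may be shared with those. Adjusted p of these 20 genes lay between 2.98e-05 and 0.00286 (limma, Benjamini-Hochberg). In all, 299 of 28735 rows were higher and 713 lower, and 22 and 53 of these by at least 2-fold.

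Genes of the cell cycle fell almost as a group at 12 J/cm2 after 24 h. Of 60 measured members 53 fell, 0 rose and 7 did not pass, against 57 lower and 1 higher adjusted over the list alone, with a median change of -0.78. KIF20A, a kinesin of cytokinesis, fell by 1.20 ± 0.07, the mitotic activator CDC20 by 1.12 ± 0.08, cyclin B1 (CCNB1) by 0.96 ± 0.06 and cyclin A2 (CCNA2) by 0.95 ± 0.06. Of 42 replication-dependent histone genes 37 fell, 0 rose and 5 did not pass, against 41 lower adjusted over the list alone, with a median change of -0.57. H1-5 fell by 0.86 ± 0.08, H2BC3 by 0.66 ± 0.07, H2AC17 by 0.63 ± 0.06 and H1-1 by 0.60 ± 0.06. Histone genes are close copies of each other, so single members are uncertain. The camera test gave adjusted p = 1.70e-79 for the cell cycle and 1.21e-51 for the histones, and adjusted p = 0.0584 and 0.0429 with an estimated correlation. KIF20A did not pass with cyclic loess (adjusted p = 0.198).

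**Figure D3:**
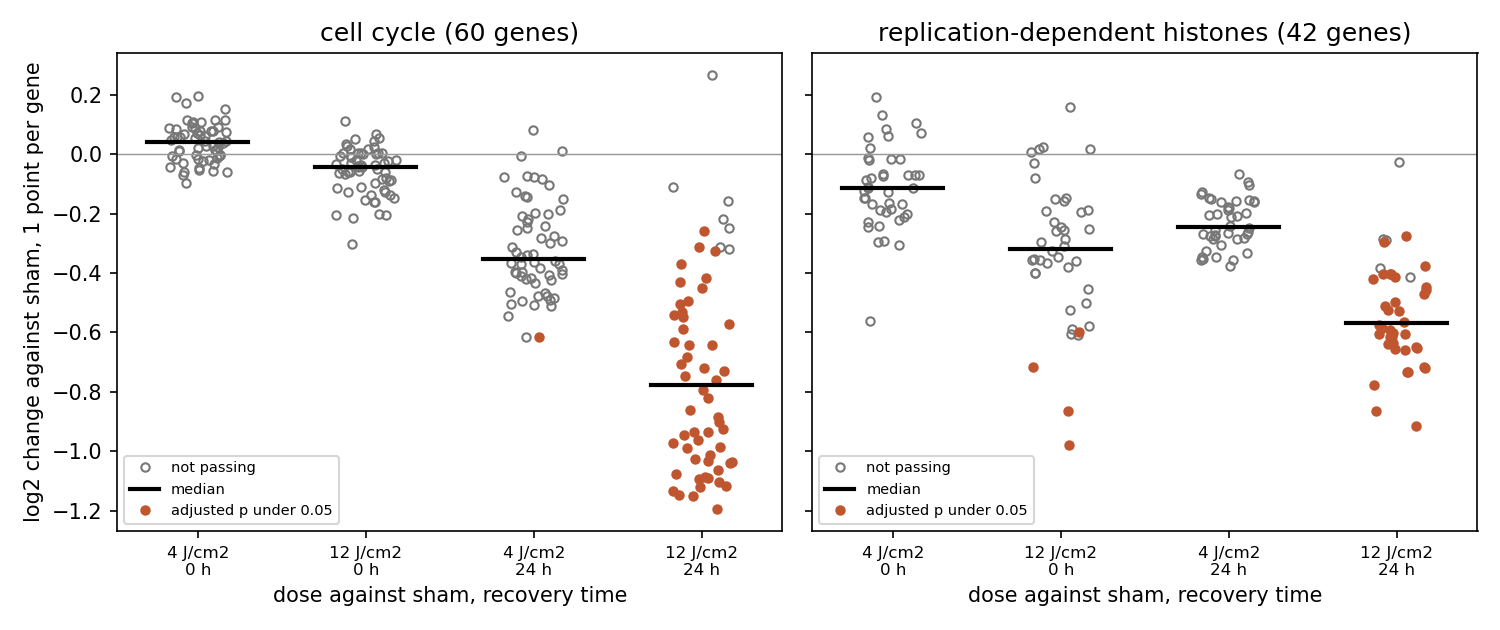
Log2 change against sham of each measured gene of the cell cycle list (60 genes) and of the histone list (42 genes) at each dose and recovery time; bars are medians and filled points pass at adjusted p under 0.05. At 12 J/cm2 and 24 h the medians are -0.78 and -0.57, with 53 and 37 genes passing, and at 12 J/cm2 and 0 h the medians are -0.04 and -0.32, with 0 and 4 passing.

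Of the 22 matrix metalloproteinases and their inhibitors, 6 rose, 1 fell and 15 did not pass at 12 J/cm2 after 24 h, against 8 higher and 1 lower adjusted over the list alone. Besides MMP1 and MMP3, MMP14, a membrane-bound collagenase, rose by 0.70 ± 0.08 (adjusted p = 0.000607), and the inhibitor TIMP3 fell by 0.44 ± 0.07 (adjusted p = 0.00362). Of 42 genes of the fibrillar and other matrix 2 rose, 6 fell and 34 did not pass, against 4 higher and 14 lower adjusted over the list alone. Fibrillin-2 (FBN2) fell by 1.23 ± 0.11, COL8A1 by 0.75 ± 0.11, COL11A1 by 0.63 ± 0.08 and COL12A1 by 0.45 ± 0.07. Camera gave adjusted p = 0.000320 for the metalloproteinases (higher) and 0.000779 for the matrix genes (lower), and adjusted p = 0.585 and 0.721 with an estimated correlation. TIMP3 and COL12A1 did not pass without replicate 2 of the 12 J/cm2 24 h group (adjusted p = 0.0599 and 0.0668), nor COL12A1 without replicate 2 of the 24 h sham group (adjusted p = 0.0530).

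Of 15 genes of contractile smooth muscle 4 fell, 0 rose and 11 did not pass (7 lower and 1 higher adjusted over the list alone). The list was called lower (camera adjusted p = 0.000820, and adjusted p = 0.630 with an estimated correlation), but not with bright rows only (adjusted p = 0.0808). The actin-binding protein TAGLN fell by 1.06 ± 0.11, ACTG2 by 0.96 ± 0.17, SYNPO2 by 0.71 ± 0.08 and CNN1 by 0.41 ± 0.09. TAGLN and CNN1 also stand in the list of TGF-beta targets, of whose 24 members 3 fell and 2 rose (8 lower and 3 higher adjusted over the list alone). The third that fell was IGFBP3, and PMEPA1 rose by 0.40 ± 0.06. Of 32 growth factors and receptors 5 fell and 1 rose (6 and 1 adjusted over the list alone). FGF1 fell by 0.95 ± 0.10, IGFBP5 by 0.96 ± 0.14 and ANGPT1 by 0.80 ± 0.11, while HGF rose. With cyclic loess FGF1 had an adjusted p = 0.0615. Camera gave adjusted p = 0.0301 for the TGF-beta and for the growth factor lists, and adjusted p = 0.777 for both with an estimated correlation. The first did not pass without replicate 1 of the 12 J/cm2 24 h group (adjusted p = 0.124), nor the second without replicate 1 of the 24 h sham group (adjusted p = 0.0711) or with cyclic loess (adjusted p = 0.0752).

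Of 29 genes driven by ATF4 or the unfolded protein response 6 fell and 1 rose (9 and 3 adjusted over the list alone). Those that fell included enzymes that make serine and asparagine, PSAT1 (-0.98 ± 0.13), ASNS (-0.71 ± 0.10) and PHGDH (-0.69 ± 0.08), and the lipoprotein receptor VLDLR (-0.53 ± 0.08). Of 27 genes of hypoxia and glycolysis 3 fell and 0 rose (10 lower adjusted over the list alone), namely PFKFB4 (-0.55 ± 0.09), ALDOC (-0.30 ± 0.07) and PFKFB3 (-0.28 ± 0.07). Of 23 NRF2 targets, which serve antioxidant defence, 2 rose and 0 fell (4 higher and 1 lower adjusted over the list alone), namely EPHX1 (0.39 ± 0.09) and glutathione reductase GSR (0.35 ± 0.07). SLC7A11, of the same list, was at -0.38 ± 0.10 and NQO1 at 0.25 ± 0.06, neither passing (adjusted p = 0.0721 and 0.0740). Of 26 genes of nucleotide excision repair 1 fell, the damage sensor DDB2 (-0.52 ± 0.07), and 0 rose (3 lower adjusted over the list alone). Camera gave adjusted p = 0.00164 for the ATF4 list, 1.87e-06 for hypoxia, 0.000766 for NRF2 and 0.0424 for excision repair, and adjusted p = 0.721, 0.417, 0.721 and 0.829 with an estimated correlation. The excision repair list did not pass without replicate 1 of the 24 h sham group or of the 12 J/cm2 24 h group. It was also lost with cyclic loess (camera adjusted p = 0.0601) and with bright rows only (camera adjusted p = 0.232).

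Of 33 p53 targets 1 rose (GDF15) and 4 fell (1 and 5 adjusted over the list alone), among them PLK2 (-0.53 ± 0.07), DDB2 and TRIM22 (-0.35 ± 0.07), and the list did not pass (camera adjusted p = 0.215). None of 30 immediate early genes passed at this time, over all rows or adjusted over the list alone (camera adjusted p = 0.630). IER3 was at 0.32 ± 0.09 (adjusted p = 0.114). The count of 1012 passing rows fell to 391 without replicate 1 of the 24 h sham group, 458 without replicate 2 and 361 without replicate 2 of the 12 J/cm2 24 h group. It rose to 1550 with each array's median subtracted, 1523 with quantile normalization, 1695 with medians subtracted by class and 1516 without replicate 2 of the 4 J/cm2 0 h group. CNN1, ALDOC, PFKFB3, GSR, EPHX1 and TRIM22 each failed to pass without at least 3 of the 4 arrays in turn (adjusted p up to 0.283, 0.376, 0.357, 0.245, 0.210 and 0.218). With quantile normalization ALDOC and PLK2 did not pass (adjusted p = 0.456 and 0.393).

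At 4 J/cm2 after 24 h 5 rows passed, and each was a gene that also passed in the same direction at 12 J/cm2. MMP1 rose 1.45-fold. MAMDC2 fell by 1.04 ± 0.13 (limma adjusted p = 0.0436), IGFBP3 by 0.73 ± 0.08 (0.0309), KIF20A by 0.62 ± 0.07 (0.0344) and the mitotic spindle gene HMMR by 0.60 ± 0.06 (0.0309). Of 60 cell cycle genes 1 passed over all rows and 44 were lower adjusted over the list alone, with a median change of -0.35. CCNB1 was at -0.48 ± 0.06 (adjusted p = 0.0624). Of 42 histone genes 0 passed over all rows and 22 were lower adjusted over the list alone, with a median of -0.25. H2BC3 was at -0.35 ± 0.07 (adjusted p = 0.258). Camera gave adjusted p = 4.36e-66 and 5.60e-38 for these lists, and adjusted p = 0.0900 for both with an estimated correlation. The metalloproteinases (1 higher of 22, and 5 higher with 1 lower adjusted over the list alone, camera adjusted p = 0.00704), TGF-beta targets (1 lower of 24, adjusted p = 0.0189), hypoxia genes (0 of 27, adjusted p = 0.0200) and keratinocyte markers (0 of 16, adjusted p = 0.0454) also passed, each with adjusted p = 0.984 with an estimated correlation, and none of these 4 passed without replicate 1 of the 24 h sham group (adjusted p = 0.108, 0.0677, 0.190 and 0.400). Of genes outside these lists, DDB2 was at -0.15 ± 0.07 and XPC, a sensor of bulky DNA damage, at 0.28 ± 0.09 (adjusted p = 0.932 and 0.590), the immediate early gene IER2 at 0.14 ± 0.07 (0.945), the antioxidant gene HMOX1 at -0.30 ± 0.20 (1.00) and COL8A1 at -0.45 ± 0.11 (0.362). Without any 1 of the 4 arrays the count was 0, and without replicate 2 of the 4 J/cm2 0 h group it was 11. Subtracting each array's median gave 35 rows and quantile normalization 254, and with only these arrays in the fit 1 row passed. Cyclic loess ended the calls of KIF20A (adjusted p = 0.835), MAMDC2 and MMP1 (adjusted p = 0.0581 for both).

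Between 12 and 4 J/cm2 at 24 h 94 rows were higher and 184 lower at the higher dose. SLC7A8 was higher by 1.91 ± 0.13, IL33 by 1.48 ± 0.18, DCSTAMP by 1.25 ± 0.17, GDF15 by 1.20 ± 0.15 and TFPI2 by 1.02 ± 0.14. The lower genes were led by HHIP (-1.22 ± 0.17), KRT34 (-1.17 ± 0.21), EDN1 (-1.12 ± 0.08), the cardiac and stretch-responsive gene ANKRD1 (-1.08 ± 0.12) and TENM2 (-1.05 ± 0.17), with limma adjusted p from 0.000892 to 0.0329 over these 10 genes. Of 60 cell cycle genes 29 were lower (54 adjusted over the list alone), among them TYMS (-0.66 ± 0.08), CDC20 (-0.65 ± 0.08) and CCNA2 (-0.53 ± 0.06), and of 42 histone genes 8 were lower (34 lower and 1 higher adjusted over the list alone), among them H1-5 (-0.60 ± 0.08). MMP10 was higher by 0.45 ± 0.07, and of the ATF4 list ASNS (-0.57 ± 0.10) and PHGDH (-0.48 ± 0.08) were lower. FBN2 was lower by 0.85 ± 0.11 and TAGLN by 0.84 ± 0.11. Camera called 8 lists, the metalloproteinases and NRF2 targets higher and the ATF4, cell cycle, histone, matrix, hypoxia and smooth muscle lists lower, and 0 with an estimated correlation (lowest adjusted p = 0.127). With quantile normalization the metalloproteinases and the ATF4 list did not pass (adjusted p = 0.186 and 0.0515). The count of 278 was 2 without either array of the 4 J/cm2 24 h group, 4 without replicate 2 of the 12 J/cm2 24 h group and 476 without replicate 2 of the 4 J/cm2 0 h group. With only the arrays of these groups in the fit it was 0. With quantile normalization IL33 did not pass (adjusted p = 0.132) and TFPI2 was at -0.13. That method gives every array the same distribution of centred values, so it can itself remove large differences between doses. With cyclic loess KRT34 and CDC20 did not pass (adjusted p = 0.0788 and 0.0773).

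**Figure D4:**
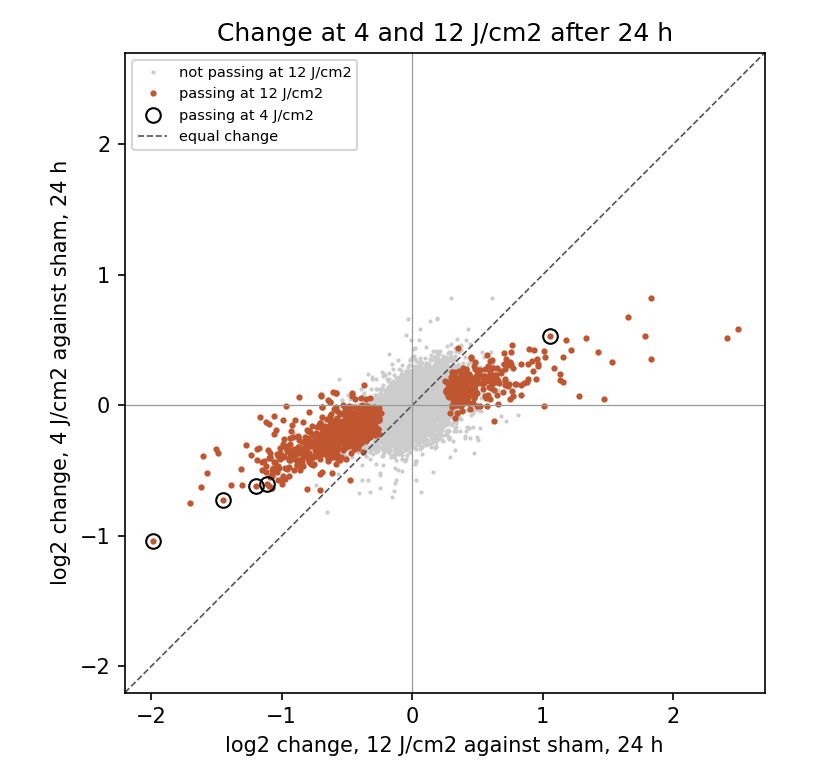
Log2 change against sham at 24 h of every row, at 12 J/cm2 (horizontal) and at 4 J/cm2 (vertical); coloured points pass at 12 J/cm2 and circles pass at 4 J/cm2. Of the 1012 rows that pass at 12 J/cm2, 980 have the same sign at 4 J/cm2.

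Both doses at 24 h were set against the same sham arrays, which makes their changes agree in part by chance. Of the 1012 rows that passed at 12 J/cm2, 96.8% had the same sign at 4 J/cm2, against 91.8% in simulated unchanged groups. The simulation gave neither dose an effect and took the rows with the largest noise at 12 J/cm2. For rows changed at 12 J/cm2 alone the agreement was not simulated, so 91.8% does not give the part due to shared arrays. The changes correlated across rows, which are not independent, with r = 0.586 against a simulated 0.499. Their covariance was 0.0107 against a simulated 0.00474, a difference of 0.00597. Of the 5 rows called at 4 J/cm2, 5 were called at 12 J/cm2 in the same direction, where independent lists give 0.0104 higher and 0.0993 lower. The 2 sham arrays were not divided between the doses, and the overlap was not simulated with shared arrays, so part of the excess may come from them. The median ratio of the change at 4 J/cm2 to that at 12 J/cm2 was 0.38 over the 1012 rows, with quartiles of 0.25 and 0.48. Simulated unchanged groups with shared sham arrays gave 0.498. That value holds for rows picked by noise alone, so it is no baseline for rows with a real change. How far the shared arrays moved the observed ratio was not measured, and no dose relation is drawn from it.

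Directly after 12 J/cm2, at 0 h, 8 rows were lower and 0 higher than sham. The 6 named genes were H1-3 (-0.98 ± 0.09, limma adjusted p = 0.00824), CRYBG3 (-0.91 ± 0.06, 0.000528), H3C12 (-0.86 ± 0.08, 0.00824), H1-5 (-0.72 ± 0.08, 0.0124), H3C1 (-0.60 ± 0.08, 0.0495) and KMT2D, a methyltransferase of histone H3 lysine 4 (-0.53 ± 0.07, 0.0496). Of 42 histone genes 4 fell, 0 rose and 38 did not pass, against 28 lower adjusted over the list alone, with a median of -0.32 (camera adjusted p = 4.84e-25, and adjusted p = 0.222 with an estimated correlation). The cell cycle list, with 0 of 60 passing and a median of -0.04, did not pass (camera adjusted p = 0.0783). Of 46 histone H3 methyltransferases and demethylases 1 fell (5 adjusted over the list alone), with KMT2C at -0.40 ± 0.07 and KMT2A at -0.35 ± 0.07 (adjusted p = 0.102 and 0.131). That list passed (camera adjusted p = 1.29e-09, and adjusted p = 0.799 with an estimated correlation), but its bright members span a median of 68.4 kb of the genome, and all bright genes of like span were at -0.09.

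The immediate early genes had 0 of 30 members passing over all rows and 5 higher adjusted over the list alone at 12 J/cm2 and 0 h. NR4A2 was at 0.72 ± 0.16, FOS at 0.48 ± 0.11, FOSB at 0.43 ± 0.11 and DUSP1 at 0.28 ± 0.06 (adjusted p = 0.150, 0.157, 0.185 and 0.142). Camera called the list higher (adjusted p = 0.00481, and adjusted p = 0.799 with an estimated correlation), but not without replicate 2 of the 0 h sham group (adjusted p = 0.0631). Camera also called the metallothioneins higher (0 of 9 members passing, median 0.15, adjusted p = 0.00146). It called lower the matrix genes (0 of 42, 5 lower adjusted over the list alone, adjusted p = 0.00146), with FBN2 at -0.55 ± 0.11 and FBN1 at -0.38 ± 0.07, and the growth factors and receptors (0 of 32, 2 lower adjusted over the list alone, adjusted p = 0.00146), with EGFR at -0.27 ± 0.06. The cholesterol synthesis list (0 of 18, adjusted p = 0.0376) was lower, and the keratinocyte (0 of 16, adjusted p = 0.0309) and immune cell markers (0 of 19, adjusted p = 0.00310) higher. With an estimated correlation these gave adjusted p = 0.222 for the metallothioneins, 0.799 for the growth factors and 0.834 for the other 4. Those 4 were also lost on leaving out an array, the matrix list without replicate 2 of the 0 h sham group (adjusted p = 0.0626), the immune cell markers without its replicate 1 (0.0924), and the cholesterol and keratinocyte lists without its replicate 1 (0.185 and 0.279) or replicate 2 of the 12 J/cm2 0 h group (0.281 and 0.0573). With bright rows only these 4 and the growth factors did not pass (adjusted p = 0.0516 to 0.341). Part of these lists' changes went with genomic span, a comparison chosen after the values were seen. Less the median of bright genes of like span, the median of bright members went from -0.15 to -0.06 for the H3 methylation list, from -0.12 to -0.01 for the growth factors, from -0.09 to -0.04 for the matrix genes, from 0.07 to 0.03 for the immediate early genes, from 0.15 to 0.12 for the metallothioneins and from -0.35 to -0.38 for the histones. The NRF2 target HMOX1 was at 0.54 ± 0.20 (adjusted p = 0.274) and the p53 target SESN1 at -0.37 ± 0.10 (adjusted p = 0.178). The count of 8 became 1 without replicate 1 of the 0 h sham group or either array of the 12 J/cm2 0 h group, 222 (179 lower) without replicate 2 of the 0 h sham group, and 30 (24 lower) without replicate 2 of the 4 J/cm2 0 h group. It was 159 (128 lower, 31 higher) with each array's median subtracted, 211 (156 lower, 55 higher) with quantile normalization, 12 (9 lower, 3 higher) with cyclic loess and 0 with only the arrays of these groups in the fit.

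Directly after 4 J/cm2 0 rows passed in limma, while 3649 had an unadjusted limma p under 0.05. At 12 J/cm2 and 0 h, with a median change over all rows of 0.0044, 3962 did. The median change over all rows at 4 J/cm2 was 0.09, because of the array that lay above the others, and -0.0004 without that array. The lowest t values were those of CRYBG3 (-0.56 ± 0.06, adjusted p = 0.0618), H1-3 (-0.56 ± 0.09, 0.378), PANK2 (-0.43 ± 0.07), C1QTNF9B (-0.57 ± 0.12) and WIF1 (-0.34 ± 0.08), and the highest those of IL20RB (0.37 ± 0.06), KLHL38 (0.46 ± 0.08), TMEM229B (0.80 ± 0.14), AHSP (0.41 ± 0.07) and IFNA5 (0.43 ± 0.08), none of which passed. Both doses at 0 h were set against the same sham arrays, and their changes correlated at r = 0.662 against 0.500 in simulated unchanged groups. Low values of CRYBG3, H1-3 and the histone genes at both doses are therefore not independent findings. Camera called the histone genes lower (0 of 42 passing, 4 lower adjusted over the list alone, median -0.11, adjusted p = 6.25e-29, and adjusted p = 0.174 with an estimated correlation). It called 6 other lists lower and the immune cell markers higher (0 of 19 passing, median 0.18), all with adjusted p of 0.819 or more with an estimated correlation. Of the 6, the immediate early (median 0.05), cell cycle (0.04), growth factor (0.01) and hypoxia (0.00) lists had medians above 0, and the matrix and H3 methylation lists had medians of -0.01 and means of 0.01 and 0.00, so the test differed in sign from the median in the first 4 of these lists and from the mean in the last 2. Of the members, EGR1 was at -0.30 ± 0.11, HMOX1 at 0.76 ± 0.20, SESN2 at 0.38 ± 0.08, MMP13 at 0.35 ± 0.06 and COL15A1 at 0.24 ± 0.10, none passing. Without replicate 1 of this group, which left the shifted array alone, 8066 rows passed, 7977 of them higher. Without replicate 2 the count was 0 and 2 lists passed, the histones (adjusted p = 1.36e-13) and the H3 methylation genes (adjusted p = 0.00134), both lower.

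Between 12 and 4 J/cm2 at 0 h 0 rows passed in limma, and 4089 had an unadjusted p under 0.05. H3C12 was at -0.56 ± 0.08, SIK3 at -0.41 ± 0.06, H1-5 at -0.48 ± 0.08, H4C9 at -0.40 ± 0.07 and CRYBG3 at -0.35 ± 0.06, while FOS was at 0.48 ± 0.11, NFKBIZ at 0.36 ± 0.08, CXCL2 at 0.35 ± 0.09, MIR21 at 0.77 ± 0.21 and FOXA2 at 0.24 ± 0.07, with adjusted p from 0.225 to 0.270. Camera called 8 lists, the immediate early genes higher (1 of 30 adjusted over the list alone, adjusted p = 2.54e-15) and the histones lower (19 of 42 adjusted over the list alone, adjusted p = 8.80e-09) among them, with adjusted p = 0.0794 and 0.450 with an estimated correlation. The heat shock, hypoxia and inflammatory lists were called higher with medians of -0.02, -0.03 and -0.02, with adjusted p = 0.904, 0.904 and 0.447 with an estimated correlation. Without replicate 2 of the 4 J/cm2 0 h group these lists did not pass (adjusted p = 0.301, 0.875 and 0.0768), and without replicate 1 the histone, TGF-beta and H3 methylation lists did not (adjusted p = 0.211, 0.367 and 0.260). The metallothioneins were called higher and the TGF-beta and H3 methylation lists lower, with adjusted p = 0.0794, 0.904 and 0.904 with an estimated correlation. The TGF-beta list was also lost with quantile normalization (adjusted p = 0.0537) and cyclic loess (adjusted p = 0.106). Without replicate 1 of the 4 J/cm2 0 h group the count was 6255, of which 6212 were lower.

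The comparison of recovery times asked whether the effect of a dose differed between 24 h and 0 h. At 12 J/cm2 it was higher at 24 h for 167 rows and lower for 149. SLC7A8 led the first (2.57 ± 0.19, limma adjusted p = 0.00140), followed by MMP3, DCSTAMP (1.87 ± 0.25), IL33 (1.82 ± 0.26) and HGF (1.61 ± 0.19). MAMDC2 (-1.55 ± 0.18), KRT34 (-1.48 ± 0.29), LCE2B (-1.42 ± 0.18), IGFBP3 (-1.35 ± 0.11) and PLCB4 (-1.34 ± 0.17) led the second. Of 60 cell cycle genes 35 had a lower effect at 24 h (53 adjusted over the list alone), among them CDC20 (-1.23 ± 0.11) and KIF20A (-1.20 ± 0.10), with a median of -0.72 (camera adjusted p = 4.84e-63, and adjusted p = 0.200 with an estimated correlation). Of 42 histone genes 1 did, H4C3 (-0.60 ± 0.09), or 4 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 3.19e-10, and adjusted p = 0.708 with an estimated correlation). MMP14 had a higher effect at 24 h (0.79 ± 0.11), and TAGLN (-1.04 ± 0.15), PSAT1 (-1.07 ± 0.18) and PHGDH (-0.72 ± 0.12) lower ones. Camera also called the metalloproteinases (adjusted p = 0.00295), NRF2 targets (0.0164) and H3 methylation genes (0.00579) higher, and the ATF4 (0.0164), hypoxia (0.00418) and smooth muscle lists (0.0164) lower, with an adjusted p of 0.780 or more with an estimated correlation. Without 1 array or another the NRF2, H3 methylation, ATF4 and smooth muscle lists did not pass (adjusted p up to 0.133, 0.168, 0.0638 and 0.0794). KMT2C and KMT2D were at 0.40 ± 0.10 and 0.39 ± 0.10, not passing (adjusted p = 0.101 and 0.103). The count of 316 fell to 55 and 61 without an array of the 12 J/cm2 0 h group, 77 and 96 without one of the 24 h sham group, 99 without replicate 2 of the 12 J/cm2 24 h group and 138 (45 higher, 93 lower) without replicate 1 of the 0 h sham group, and rose to 626 without replicate 2 of the 4 J/cm2 0 h group. It was 320 (222 higher, 98 lower) without replicate 2 of the 0 h sham group, so the balance of directions moved with these arrays. With cyclic loess KRT34, LCE2B and KIF20A did not pass (adjusted p = 0.167, 0.743 and 0.321).

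For 4 J/cm2 the effect differed between recovery times at 1 row, which has no gene symbol. HMMR (-0.74 ± 0.09), IGFBP3 (-0.83 ± 0.11), KIF20A (-0.69 ± 0.10), CCNB1 (-0.60 ± 0.09) and DEPDC1 (-0.72 ± 0.12) had the lowest t values and did not pass (adjusted p from 0.0954 to 0.308). MMP1 (0.51 ± 0.09), CRYBG3 (0.45 ± 0.09), CDCP1 (0.53 ± 0.11), PANK2 (0.49 ± 0.10) and RRAGD (0.48 ± 0.11) had the highest and did not pass (adjusted p from 0.321 to 0.582). Of 60 cell cycle genes 0 passed over all rows and 39 were lower adjusted over the list alone (camera adjusted p = 1.93e-32, and adjusted p = 0.786 with an estimated correlation). Camera called 4 other lists higher, with adjusted p = 0.0184 for the metalloproteinases and for the immediate early genes, 0.0221 for the H3 methylation genes and 0.0289 for the matrix genes, and adjusted p = 0.969 for each with an estimated correlation. The medians of the last 3 were -0.02, 0.00 and -0.02, higher only relative to all rows, and without replicate 2 of the 4 J/cm2 0 h group none of the 4 passed (adjusted p = 0.166 to 0.778). Without replicate 1 of the 4 J/cm2 0 h group 1047 rows passed, 1026 of them lower, MMP1 among those higher (adjusted p = 0.0373), and without any other array of these groups 0 passed. With quantile normalization 26 rows passed, 15 lower and 11 higher.

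Sham arrays at 24 h and 0 h, which received no light, differed at 469 rows, 164 higher and 305 lower at 24 h. Cholesterol synthesis fell, with 10 of 18 members lower, 0 higher and 8 not passing (16 lower adjusted over the list alone), among them HMGCS1 (-0.78 ± 0.09), DHCR7 (-0.74 ± 0.07), the fatty acid desaturase SCD (-0.60 ± 0.07) and SQLE (-0.40 ± 0.06). Of 60 cell cycle genes 6 rose (26 adjusted over the list alone), among them CDK1 (0.60 ± 0.12), TOP2A (0.42 ± 0.08) and CCNA2 (0.38 ± 0.06). Of 33 p53 targets 4 fell (10 adjusted over the list alone), namely PLK2 (-0.92 ± 0.07), GDF15 (-0.71 ± 0.15), SESN2 (-0.47 ± 0.08) and EDA2R (-0.35 ± 0.07). Of 24 TGF-beta targets 2 rose (6 higher and 2 lower adjusted over the list alone), IGFBP3 (1.02 ± 0.08) and BHLHE40 (0.46 ± 0.07), and of 9 metallothioneins 1 rose, MT1M (0.37 ± 0.08). Camera gave adjusted p = 8.37e-23 for cholesterol synthesis, 1.25e-20 for the cell cycle, 0.000553 for p53 targets, 0.0123 for TGF-beta targets and 0.00907 for metallothioneins, and adjusted p = 0.226, 0.573, 0.972, 0.972 and 0.380 with an estimated correlation. The last 2 did not pass without replicate 1 of the 0 h sham group (adjusted p = 0.0611 for both). MMP1 and MMP3 were at -0.03 ± 0.06 and 0.40 ± 0.14 (limma adjusted p = 0.963 and 0.252). The count of 469 fell to 68 and 82 without an array of the 24 h sham group and to 137 (71 higher, 66 lower) without replicate 1 of the 0 h sham group, and rose to 853 without replicate 2 of the 4 J/cm2 0 h group. It was 398 (56 higher, 342 lower) without replicate 2 of the 0 h sham group, and 81 with only the arrays of these groups in the fit, where CCNA2, SESN2, BHLHE40 and MT1M were among those not passing (adjusted p = 0.0949, 0.0888, 0.0760 and 0.204).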

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

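No test in this part was chosen after its result was seen. Each result was picked out by a test of the difference between the recovery times in the effect of a dose. At 12 J/cm2 316 rows and 8 gene lists differed between 24 h and 0 h, and at 4 J/cm2 1 row and 5 lists did. With an estimated correlation 0 lists passed in either comparison (lowest adjusted p = 0.200 at 12 J/cm2 and 0.786 at 4 J/cm2). Of the 5 lists at 4 J/cm2, the immediate early, H3 methylation and matrix lists had medians of -0.02, 0.00 and -0.02, and the last 2 turned direction with fry. The genes with the largest differences at 12 J/cm2 were SLC7A8 (2.57), MMP3 (1.98), DCSTAMP (1.87), IL33 (1.82) and HGF (1.61), higher at 24 h, and MAMDC2 (-1.55), KRT34 (-1.48), LCE2B (-1.42), IGFBP3 (-1.35) and PLCB4 (-1.34), lower at 24 h. MMP1 differed by 1.07.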

How the results depend on the processing

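The alternatives that keep bright rows only, subtract medians by class, or leave out replicate 2 of the 4 J/cm2 0 h group where it is not compared were chosen after seeing the data. The filter on row means was not run because centring leaves no means, and the fit without a trend is the one used. Each group held 2 arrays, so leaving 1 out leaves a lone array that is assumed to vary like the other groups. Levels were lost in centring, so what signal over background limits could not be measured. On leaving out an array, calls of named genes were kept in 483 of 705 cases, lost in 222 and reversed in 0, and named genes that had not passed came to pass in 94 of 1282 cases. MMP1 and MMP3 passed at 12 J/cm2 after 24 h under every alternative examined for them. Robust moderation, rows with 1 symbol only and a change of at least 2-fold were not examined for these genes. Where no cause is given, the cause was not tested.

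Robust moderation gave 5 rows at 12 J/cm2 0 h. Rows with 1 symbol gave 1 at 4 J/cm2 0 h, 9 at 4 J/cm2 24 h and 0 for the difference between times at 4 J/cm2. Quantile normalization gave 2 at 4 J/cm2 0 h, 211 at 12 J/cm2 0 h, 254 at 4 J/cm2 24 h, 1523 at 12 J/cm2 24 h, 1 for 12 against 4 J/cm2 at 0 h, 26 and 591 for the differences between times at 4 and 12 J/cm2, 1209 for sham, and 219 shared by the doses at 24 h. With it MMP3 at 4 J/cm2 24 h was 0.99 (adjusted p = 0.00568). For 12 against 4 J/cm2 at 24 h it gave 0.0473 for MMP1 (0.806), -0.0506 for MMP3 (0.900) and -0.13 for TFPI2 (0.584), the last 2 reversed. Quantile normalization gives every array the same distribution of centred values. Genes near the top at both doses can therefore come out alike, so these values do not test the difference between doses. With it the difference between times at 4 J/cm2 was 0.78 for MMP1 (0.0175) and 1.09 for MMP3 (0.0499). Subtracted medians gave 2, 159, 35 and 1550 for the doses against sham in the same order, 546 for 12 against 4 J/cm2 at 24 h, 3 and 723 for the differences between times and 950 for sham. Cyclic loess gave 10 at 4 J/cm2 24 h, 463 for 12 against 4 J/cm2 at 24 h, 0 and 610 for the differences between times, 839 for sham, 2 lists for the difference between times at 4 J/cm2, and 0.53 for MMP1 at 4 J/cm2 24 h (0.0581).

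With only the arrays compared, which leaves fewer degrees of freedom, 0 rows passed at 12 J/cm2 0 h, 1 at 4 J/cm2 24 h, 0 for 12 against 4 J/cm2 at 24 h, 0 for the difference between times at 4 J/cm2 and 81 for sham. MMP1 was then at 0.53 at 4 J/cm2 24 h (adjusted p = 0.0837) and 12 against 4 J/cm2 at 24 h at 0.52 for MMP1 (0.0812) and 1.01 for MMP3 (0.0835). A change of at least 2-fold left 1 at 12 J/cm2 0 h, 1 at 4 J/cm2 24 h, 75 at 12 J/cm2 24 h, 14 for 12 against 4 J/cm2 at 24 h, 0 and 63 for the differences between times, 45 for sham and 1 shared. Bright rows only gave 1, 351 and 45 at 4 J/cm2 0 h, 12 J/cm2 0 h and 4 J/cm2 24 h, 669 for 12 against 4 J/cm2 at 24 h, 2 and 853 for the differences between times, 800 for sham and 44 shared, with MMP3 at 4 J/cm2 24 h at 0.82 (0.0310) and 5, 3 and 5 lists at 4 J/cm2 0 h, 4 J/cm2 24 h and for the difference between times at 12 J/cm2. Medians subtracted by class gave 2, 105, 27 and 1695 for the doses against sham, 651 for 12 against 4 J/cm2 at 24 h, 4 and 752 for the differences between times, 1030 for sham and 27 shared, with 5 lists at 4 J/cm2 0 h and 1 for the difference between times at 4 J/cm2.

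With an estimated correlation 1 list passed at 12 J/cm2 24 h and 0 in each of the other contrasts. With fry the lists passing were 0, 2, 2 and 4 for the doses against sham, 0 and 2 for 12 against 4 J/cm2 at 0 and 24 h, 0 and 1 for the differences between times, and 2 for sham. Fry tests a list against 0 and camera against the other genes, and so with fry the direction reversed at 4 J/cm2 0 h for the immediate early (adjusted p = 0.663), cell cycle (0.707), matrix (0.944) and growth factor lists (0.764), for 12 against 4 J/cm2 at 0 h for the heat shock (0.488), inflammatory (0.840) and hypoxia lists (0.290), and for the difference between times at 4 J/cm2 for the matrix and H3 methylation lists (0.914 for both). The hypoxia list for 12 against 4 J/cm2 at 0 h also reversed without replicate 2 of the 4 J/cm2 0 h group (0.875), its adjusted p on leaving out arrays going from 1.47e-05 to 0.875.

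On leaving out arrays in turn the counts ranged from 0 to 8066 at 4 J/cm2 0 h, 1 to 222 at 12 J/cm2 0 h, 0 to 11 at 4 J/cm2 24 h, 361 to 1516 at 12 J/cm2 24 h, 0 to 6255 and 2 to 476 for 12 against 4 J/cm2 at 0 and 24 h, 0 to 1047 and 55 to 626 for the differences between times, 68 to 853 for sham, and 0 to 11 for those shared. MMP1 ranged from 0.53 to 0.54 at 4 J/cm2 24 h, from 0.48 to 0.57 for 12 against 4 J/cm2 at 24 h and from 0.48 to 0.54 for the difference between times at 4 J/cm2, and MMP3 from 0.81 to 1.21 for 12 against 4 J/cm2 at 24 h. Lists passing ranged from 2 to 10 at 4 J/cm2 0 h, 2 to 6 at 4 J/cm2 24 h, 5 to 9 for 12 against 4 J/cm2 at 0 h, 3 to 9 for the difference between times at 4 J/cm2 and 3 to 7 for sham.

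The replicate numbers did not pair the samples, the deviations of same-numbered arrays correlating at -0.069 to 0.315 over 15 pairs of groups (median 0.039), with 4 above 0.1. With the replicate block 16 rows passed at 12 J/cm2 0 h and 0 for the difference between times at 4 J/cm2, and MMP1 at 4 J/cm2 24 h was 0.53 (adjusted p = 0.0586).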

Other observations

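The genes of this paragraph were chosen after their values were seen, and 2 of the tests of the explanations weighed after it (shared histone signal and a span trend between arrays) were written before their results were seen and the other 5 after the pattern was seen. Of 46 histone H3 methyltransferases and demethylases, 3 fell at 12 J/cm2 after 24 h and 0 rose (3 lower adjusted over the list alone). EZH2, which methylates H3 lysine 27, fell by 0.57 ± 0.09 (limma adjusted p = 0.00553), SUV39H1, which methylates H3 lysine 9, by 0.43 ± 0.09 (0.0237) and NSD2, which methylates H3 lysine 36, by 0.41 ± 0.09 (0.0310). The list did not pass (camera adjusted p = 0.0734). The chemokine CCL2 fell by 1.00 ± 0.10 (0.000373) and the interferon-induced IFIT1 by 1.19 ± 0.14 (0.000872), while the mitochondrial superoxide dismutase SOD2 rose by 0.38 ± 0.08 (0.0351). At 4 J/cm2 CCL2 was at -0.60 ± 0.10 and EZH2 at -0.34 ± 0.09, not passing (0.156 and 0.481).

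At 0 h after 12 J/cm2 bright genes that span more of the genome were lower, and dim genes less so. Over 9236 bright genes the change correlated with span at rho = -0.548, and the 4 pairs of arrays gave rho from -0.533 to -0.3997, against -0.129 over 7642 dim genes, genes not being independent of each other. At 12 J/cm2 and 24 h rho was -0.0245. At 4 J/cm2 and 0 h it was -0.357 (pairs of arrays from -0.387 to -0.0702), against the same sham arrays. On the single 4 J/cm2 0 h arrays the centred values correlated with span at -0.0413 and -0.133. Both lie nearer to replicate 2 of the 0 h sham group (-0.00563) than to its replicate 1 (0.321). The value at 4 J/cm2 is therefore not separate evidence of a trend. One hypothesis is that light damage stops transcription in long genes, but -0.548 is the observation that led to it and does not test it, so it stays open. A trend that differs between arrays was also tested. The largest rho between replicates was -0.333, in the 0 h sham group (0.321 on replicate 1 and -0.00563 on replicate 2, against -0.425 and -0.356 on the 12 J/cm2 arrays). It was smaller in size than that of the dose and of each of the 4 pairs of arrays, the nearest being -0.3997. A trend shared by both arrays of a group would not show between replicates, so a trend between arrays stays open.

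Histone genes were lower at 0 h after 12 J/cm2 by a median of 0.32. A lower share of cells in S phase, at the 24 h ratio of both lists, would put the cell cycle list near -0.43. It was at -0.0434. That ratio need not hold directly after exposure, so a lower share of S-phase cells stays open. A shift of whole arrays or level classes would move the medians of the classes as far, and these differed between the groups by at most 0.0310, with -0.32 ± 0.03 left after they were subtracted (-0.31 ± 0.04 after quantile normalization, which moved other genes by up to 0.24). Signal shared between copies of 1 histone class would spare the other classes, and 5 of 5 classes had medians under -0.1. The H4 median was -0.11, with 5 of 8 members below 0. Sharing of signal within every class was not tested. These values argue against a shift of arrays or level classes, and against sharing in 1 histone class alone, as the whole cause. Scaling that depends on level within a class stays open, since levels were removed by centring, and so does transcript length, which was not analysed here (the histone list has a median span of 0.49 kb).

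Replicate 2 of the 4 J/cm2 0 h group lay above the other arrays. If light were the cause, the other replicate would lie high as well, and its median was -0.00736, beside 0.00186 for the highest array of the other groups. Array scaling or background was tested by the difference of dim and bright medians, which was 0.103 on this array and at most 0.0432 in size on the others. That is larger, but by less than the 3 times set for the test. An even scaling of the array would move both classes alike and leave no such difference, so the test cannot address it. Both class medians of this array were raised, 0.22 over dim rows and 0.12 over bright rows. Scaling and background, tested as 1 explanation, both stay open.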
